A study of Mus musculus with 12 samples.

How the data were processed

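Gene expression was measured by RNA sequencing in 12 tumours grown under the skin from CT26, a mouse colon carcinoma line, in 4 groups of 3: solvent control, trametinib alone, radiation alone, and trametinib with radiation. Trametinib inhibits the MEK kinases. Per the labels' protocols it was given by gavage at 1 mg/kg daily, the other mice received corn oil, and irradiated tumours received 8 Gy in 1 fraction after 2 days of gavage. The labels state that the 3 tumours of a group came from different mice and that tissue was taken away from necrotic areas. RNA was extracted with TRIzol, polyadenylated RNA was selected with oligo(dT) beads, and cDNA was primed with random hexamers. The time of harvest was not given in the sources used here.

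The deposited table held estimated counts for each gene and library, which are not whole numbers in 25.9 to 27.4% of cells and were not normalized by the authors. The same table held deposited TPM values, which the authors had scaled by gene length and to a total of 1000000 per library. It also held log2 fold changes and q-values from the authors' own comparisons, made with DESeq2 per the file headers, whose settings and version were not given in the sources used here. The aligner, quantifier, strand setting and genome build were not given in the sources used here. FPKM columns, group averages and 1 further comparison of the table were not used here. The table listed 18351 genes, all typed as coding. Their coordinates overlapped the GENCODE M21 annotation of mouse build GRCm38 for 17661 of 17677 genes with an Ensembl identifier, and 74.2% of 18293 gene identifiers had the same start and end as in RefSeq on GRCm38.p6. Coordinates printed here are those of RefSeq on GRCm38.p6 for genes where the deposited start and end were the same.

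Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10, which left 13567 genes, and libraries were scaled by TMM. A quasi-likelihood model with a term for group was fitted to all 12 libraries together, with 8 residual degrees of freedom, 4.75 prior degrees of freedom and a biological coefficient of variation of 18.5%. The contrasts were each treated group against control, the combination against each single treatment, the effect of each treatment averaged over the other, and their interaction. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all tested genes. Values per group are counts scaled to 1000000 per library (CPM) with the SD over 3 tumours. Standard errors of log2 fold changes of genes are approximate. Each is the size of the fold change divided by the square root of its F statistic in the same fit.

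A set of 26 gene lists for pathways and cell types was tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists within a contrast. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in one direction, were run beside it. For each list, calls were also counted after adjustment over the list alone. The tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named, for each comparison of groups, the 5 largest rises and 5 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap of the groups, leaving out symbols that are clone or locus numbers, up to 4 members of each list with the smallest p, and 16 genes fixed by name. Its use for the averaged effects and the interaction was chosen after the data were examined.

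Total counts per library lay between 15008279 and 18773777, and the 10 most abundant genes took 6.72 to 8.76% of a library. Counts were simulated from these libraries over 13567 genes, with 200 genes changed. The changed genes all had a mean log2 CPM above 2, so recovery of less expressed genes was not measured. The test for the combination against control recovered 32.8% of genes changed 1.5-fold, 82.1% of genes changed 2-fold and 100% of those changed 4-fold, with 5.3% false calls. For trametinib against control it recovered 67.2% of 2-fold changes, for radiation averaged over trametinib 97%, and for the interaction 44.8%. The Benjamini-Hochberg threshold depends on how many genes change. It is stricter in the real trametinib and interaction contrasts, which gave 0 calls, so recovery there can be lower than in these simulations. In the simulated list test, a list moved 1.5-fold gave an adjusted p of 5.84e-11 with camera, and 0 of 25 unmoved lists passed. The simulated genes were drawn independently of each other, so that test could not show false list calls from genes that move together.

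The alternatives were size factors by RLE in place of TMM, no filter on low counts, DESeq2 1.42.0, limma voom with sample quality weights, a replicate block, each pair of groups fitted alone, limma-trend on log2(TPM + 1) for genes with a mean TPM of at least 1, and leaving out each library in turn. Offsets for trends on transcript length and GC content were added after the data were examined, with lengths and GC content for 97.9% of tested genes. Both were taken from the longest GENCODE M21 transcript of each gene. The H2, Gbp, Oas, Ifit, Tgtp and haemoglobin families hold near-identical copies, so values of single members are uncertain. Because the strand setting was not given, reads from overlapping antisense genes cannot be separated. Figures were drawn with matplotlib 3.10.9.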

Results

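The series measured the transcriptome of CT26 tumours in mice under a 2 by 2 design of trametinib and radiation, with 3 tumours from different mice in each of 4 groups. CT26 is a transplantable colon carcinoma line of BALB/c mice, which the submitters class among KRAS-mutated models. Outside the sequencing, the submitters assessed PD-L1, MHC class I molecules and cytokines, so the genes of these molecules are followed through each comparison. Library depth was similar, from 15008279 counts in trametinib tumour 1 to 18773777 in control tumour 1. Replicates of a group differed by more than sampling noise in each pair, with a chi-square per degree of freedom of 15.5 to 45.3. Control tumour 3 stood apart on the second principal component, at 49.4, where the other 11 libraries lay between -20.2 and 13.2. Its skeletal muscle list mean lay 3.75 log2 units above the control mean, and its type I interferon and T cell list means lay 0.48 and 0.52 above it. Across genes, which are not independent replicates, expression relative to the mean of all libraries followed transcript length with a Spearman rho of -0.30 to -0.19 in controls and 0.11 to 0.43 in the combination.

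Trametinib alone was compared with control to show what the drug did without radiation. The 4 MHC class II genes with the smallest p were lower in all 3 treated tumours than in all 3 controls, without passing the test. Cd74, the invariant chain that escorts MHC class II molecules, stood at 459 ± 112 CPM (SD, n = 3) against 903 ± 116 in controls, a log2 fold change of -0.97 (SE 0.19, adjusted p = 0.409 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The values were -1.02 (SE 0.24) for H2-Eb1, -0.93 (SE 0.22) for H2-Aa and -0.84 (SE 0.18) for H2-DMa. By edgeR 0 of 10 tested members of the list passed over all genes and 7 were lower when adjusted over the list alone, while DESeq2 called 5 of the 10 down over all genes and voom 0. The list median was -0.88, with camera's adjusted p = 4.02e-11 at the preset correlation and adjusted p = 0.646 with an estimated correlation. Among macrophage and monocyte genes 5 of 23 were lower when adjusted over the list alone, and the lysozyme gene Lyz2 and the monocyte chemokine receptor gene Ccr2 gave -0.58 (SE 0.14) and -1.12 (SE 0.29). That list had a median of -0.36, with camera's adjusted p = 4.63e-05 and adjusted p = 0.702 with an estimated correlation. Dendritic cells and B cells also carry class II molecules. The means of the dendritic cell list and of the B and plasma cell list lay at -0.37 ± 0.23 and -0.48 ± 0.28 (SD, n = 3) relative to controls. In the latter list B cell genes such as Cd19 and Ms4a1 fell below the filter, and Ighm and Igkc were absent from the deposited table.

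Transcripts that report ERK signalling did not pass the test under trametinib alone. Dusp6, an ERK phosphatase induced by ERK itself, stood at 125 ± 16 CPM against 161 ± 44.1 (log2 fold change -0.36, SE 0.19), Etv4 gave -0.25 (SE 0.10) and Spry4 0.07 (SE 0.22). The MEK-ERK output list had a median of -0.06 over 19 genes, with 0 calls over all genes, 0 adjusted over the list alone and camera's adjusted p = 0.368. Cd274, which encodes PD-L1, gave -0.29 (SE 0.22), and the class I genes H2-K1, H2-D1 and B2m gave 0.03 (SE 0.14), 0.01 (SE 0.13) and -0.15 (SE 0.16). The chemokine genes Cxcl9 and Cxcl10 gave -1.06 (SE 0.24) and -0.49 (SE 0.45), neither past the threshold. By edgeR 0 of 13567 genes passed, while 1137 had an unadjusted p below 0.05 where 678 are expected by chance, and DESeq2 called 31 and voom 1. The count stayed at 0 with RLE size factors, without the filter, by limma-trend on TPM and in each of 12 fits without a library.

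Radiation alone was compared with control to show what irradiation did without the drug. Tnc, the gene of the matrix glycoprotein tenascin-C, rose from 25.8 ± 8.03 to 84.1 ± 7.07 CPM (SD, n = 3), a log2 fold change of 1.71 (SE 0.19, adjusted p = 0.0111 by edgeR). It was higher in all 3 irradiated tumours, which the naming rule required of the largest rises. The interferon-related genes Cd274, Stat2, Oas2 and Gbp6 were higher in all 3 irradiated tumours than in all 3 controls without passing edgeR's test. The values were 1.08 (SE 0.21, adjusted p = 0.104) for Cd274, 1.12 (SE 0.23) for the interferon signal transducer Stat2, 1.55 (SE 0.36) for Oas2 and 1.11 (SE 0.26) for Gbp6. The type I interferon list means overlapped, with 0.48 in control 3 and 0.34 in radiation 3, while the interferon-gamma and MHC class I list means did not. Of the class I genes, Nlrc5, which encodes their transactivator, gave 0.69 (SE 0.14), H2-K1 0.44 (SE 0.14), H2-D1 0.33 (SE 0.13) and B2m 0.56 (SE 0.16). Cxcl9 gave 0.00 (SE 0.23) and Cxcl10 0.70 (SE 0.44), and the p53 targets Mdm2, Cdkn1a and Ccng1 gave 0.41 (SE 0.13), 0.11 (SE 0.10) and 0.08 (SE 0.12). When adjusted over the list alone, 15 of 25 type I interferon genes, 13 of 20 interferon-gamma genes, 12 of 23 MHC class I genes and 6 of 18 checkpoint genes were higher, and 9 of 10 adipocyte genes were lower. The medians of these 5 lists were 0.87, 0.84, 0.37, 0.67 and -4.14, each past the threshold by camera at the preset correlation and each with adjusted p = 0.503 with an estimated correlation. Over all genes edgeR called 0 members of the type I interferon, interferon-gamma and MHC class I lists, where DESeq2 called 5, 8 and 7 up. The calls were 12, 7 and 11 by voom, 3, 1 and 4 by limma-trend on TPM, and 7, 5 and 5 by edgeR without control 3. The type I median was 0.52 without radiation 2, and the MHC class I median was 0.57 on TPM, where the median of all genes also shifted, by 0.16. The T cell list had a median of 0.57, with 0 of 20 members called by edgeR over all genes, 1 by DESeq2, 5 by voom, 0 by limma-trend on TPM and 4 by edgeR without control 3. Tnc was the single call among 13567 genes, while 2444 had an unadjusted p below 0.05. DESeq2 called 510, voom 1123 and limma-trend on TPM 44, with 5 calls without the filter, 3 with the replicate block and 2 with these groups fitted alone, both falls, where Tnc did not pass (adjusted p = 0.0736). Leaving out control 3 gave 425 calls, radiation 3 gave 3, trametinib 2 gave 2, and leaving out control 1 or radiation 1 gave 0 and ended the Tnc call.

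The combination was compared with control for the joint effect of both treatments. The PD-L1 gene and part of the interferon genes rose, and 9 of 15 endothelial genes fell. Cd274 (gene 60533, chromosome 19, 29362107 to 29388095, GRCm38.p6) rose from 23.6 ± 4.67 to 59.7 ± 17.3 CPM (SD, n = 3), a log2 fold change of 1.34 (SE 0.21, adjusted p = 0.0118 by edgeR). Cldn5 (gene 12741, chromosome 16, 18776847 to 18778262), a claudin of endothelial tight junctions, fell by 2.69 on the log2 scale (SE 0.35, adjusted p = 0.00696), from 7.11 ± 0.94 to 1.10 ± 0.19 CPM. The 5 largest rises under the naming rule were in the inducible nitric oxide synthase gene Nos2 (2.52, SE 0.61), the parathyroid hormone-related protein gene Pthlh (2.38, SE 0.41), Slfn4 (2.15, SE 0.45), the collagen gene Col12a1 (1.97, SE 0.44) and the immune receptor gene Slamf7 (1.85, SE 0.38). With Cldn5, the largest falls under that rule were in Fcrls (-3.91, SE 0.84), the imprinted gene Mest (-3.06, SE 0.55), Cox6a2 (-2.93, SE 0.61), a cytochrome oxidase subunit of heart and skeletal muscle whose value was -1.73 without control 3, the library with the highest muscle list mean, and Car6 (-2.60, SE 0.30), a secreted carbonic anhydrase. For each of these genes all 3 combination tumours lay on one side of all 3 controls. The naming rule required this of the largest rises and falls, so for them it is no separate result. By edgeR 1348 of 13567 genes were called, 652 up and 696 down, with 93 rises and 133 falls of at least 2-fold. Leaving out control 2 left 16 calls, combination 3 82, control 1 654 and combination 1 779, and of the 33 called genes named for this comparison these fits kept 3 (Cldn5, Car6 and Egfl7), 11, 23 and 25, where each other left-out library kept 27 to 32. With offsets for length and GC content 453 genes were called, with these groups fitted alone 281, by DESeq2 2051, by voom 2350 and by limma-trend on TPM 2120.

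Members of the interferon and MHC class I lists were called up in the combination against control. In the type I interferon list 13 of 25 tested genes rose, 22 when adjusted over the list alone, with a median of 1.06, and Stat2 and Oas2 rose by 1.36 (SE 0.23) and 1.66 (SE 0.36). In the interferon-gamma list 10 of 20 rose, 18 adjusted over the list alone, with a median of 1.05, among them Gbp3 (1.07, SE 0.22), an interferon-induced GTPase, and Cxcl10 (1.64, SE 0.44), while Cxcl9 gave -0.17 (SE 0.23). Cxcl10 gave 0.65 without combination 2 and kept its call in 5 of 12 fits without a library. In the MHC class I list 7 of 23 rose, 8 adjusted over the list alone, with a median of 0.23. They included Nlrc5 (0.85, SE 0.14), the peptide transporter gene Tap2 (0.73, SE 0.15) and the tapasin gene Tapbp (0.73, SE 0.17), while H2-K1, H2-D1 and B2m gave 0.36 (SE 0.14), 0.28 (SE 0.13) and 0.24 (SE 0.16) and did not pass. In the endothelial list 9 of 15 fell, 12 adjusted over the list alone, with a median of -1.26, among them Egfl7 (-1.54, SE 0.19), Esam (-1.64, SE 0.25) and Emcn (-1.42, SE 0.24). These 4 lists passed by camera at the preset correlation, each with adjusted p = 0.578 with an estimated correlation, and by fry the endothelial list alone of the 4 passed (adjusted p = 0.0233). Without control 2 the calls in these 4 lists were 0, 0, 0 and 2, without combination 3 they were 3, 0, 1 and 5, without control 1 they were 2, 2, 4 and 8, and without combination 2 they were 5, 3, 5 and 8. The interferon-gamma list held 6 without trametinib 2, and the type I list held 22 without control 3. The interferon-gamma median was 0.60 without combination 2, and the MHC class I median was 0.37 without control 3 and 0.48 on TPM. On TPM the median of all genes also shifted, by 0.23. With these groups fitted alone the 4 lists held 5, 2, 2 and 9 calls, with length and GC offsets 10, 5, 8 and 9, by voom 23, 12, 9 and 9 and by limma-trend on TPM 22, 15, 14 and 7. For each called gene of these lists named here, all 3 combination tumours lay on one side of all 3 controls. The MHC class I list means overlapped, with 0.15 in combination 3 and 0.19 in control 3, and the means of the other lists did not.

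Other lists moved by fewer members in the combination against control. Of 20 p53 targets 2 rose, Mdm2 (0.82, SE 0.13), which encodes the ubiquitin ligase of p53, and Trp53inp1 (0.80, SE 0.21), with 3 adjusted over the list alone, while Cdkn1a and Ccng1 gave 0.17 (SE 0.10) and 0.21 (SE 0.12). Of 23 macrophage and monocyte genes 4 fell, 7 adjusted over the list alone: the complement gene C1qb (-0.74, SE 0.19), Lyz2 (-0.61, SE 0.14), Tyrobp (-0.66, SE 0.13) and Fcgr3 (-0.66, SE 0.19). Of 36 cell cycle genes 2 fell, 1 adjusted over the list alone, including the replicative helicase gene Mcm7 (-0.70, SE 0.15). Among 23 fibroblast and matrix genes Thbs2 (0.99, SE 0.18) and Col5a1 (0.91, SE 0.25) rose, with 3 adjusted over the list alone. Of 20 T cell genes Themis rose (1.43, SE 0.30), and among 19 cytotoxic and NK cell genes Il2rb rose (0.78, SE 0.22), while Cd8a, Cd3e, Gzmb and Ifng gave 0.92 (SE 0.34), 0.75 (SE 0.34), 0.46 (SE 0.34) and 1.12 (SE 0.52) without passing. In the T cell list DESeq2 called 5, voom 8, limma-trend on TPM 5, edgeR without control 3 7 and these groups alone 0. In the cytotoxic list DESeq2, voom and limma-trend called 2 and edgeR with RLE size factors, the replicate block or the offsets 0. In the MEK-ERK output list Emp1 rose (0.47, SE 0.11), the list median was 0.09 over 19 genes (camera's adjusted p = 0.321), and Dusp6, Etv4 and Spry4 gave -0.52 (SE 0.19), 0.02 (SE 0.10) and 0.16 (SE 0.22). Adjusted p by edgeR was 0.0118 for Mdm2 and 0.0135 to 0.0468 for the other called genes of these lists. The macrophage, cell cycle, T cell and cytotoxic lists passed by camera at the preset correlation, with adjusted p = 0.628, 0.736, 0.628 and 0.663 with an estimated correlation. All 3 combination tumours lay on one side of the controls for each called gene but Il2rb. Leaving out control 2 ended all of these calls, and leaving out combination 3 ended all but that of Mdm2. Leaving out control 1 ended those of Trp53inp1, C1qb, Mcm7, Col5a1 and Emp1, combination 1 those of Trp53inp1, C1qb, Lyz2, Fcgr3 and Col5a1, combination 2 those of Fcgr3, Col5a1 and Emp1, and control 3 those of Trp53inp1 and Fcgr3. Fcgr3 and Col5a1 were also lost without trametinib 2 or 3, Fcgr3 without radiation 1 and Col5a1 without radiation 2, and Il2rb kept its call only without control 3.

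**Figure D1:**
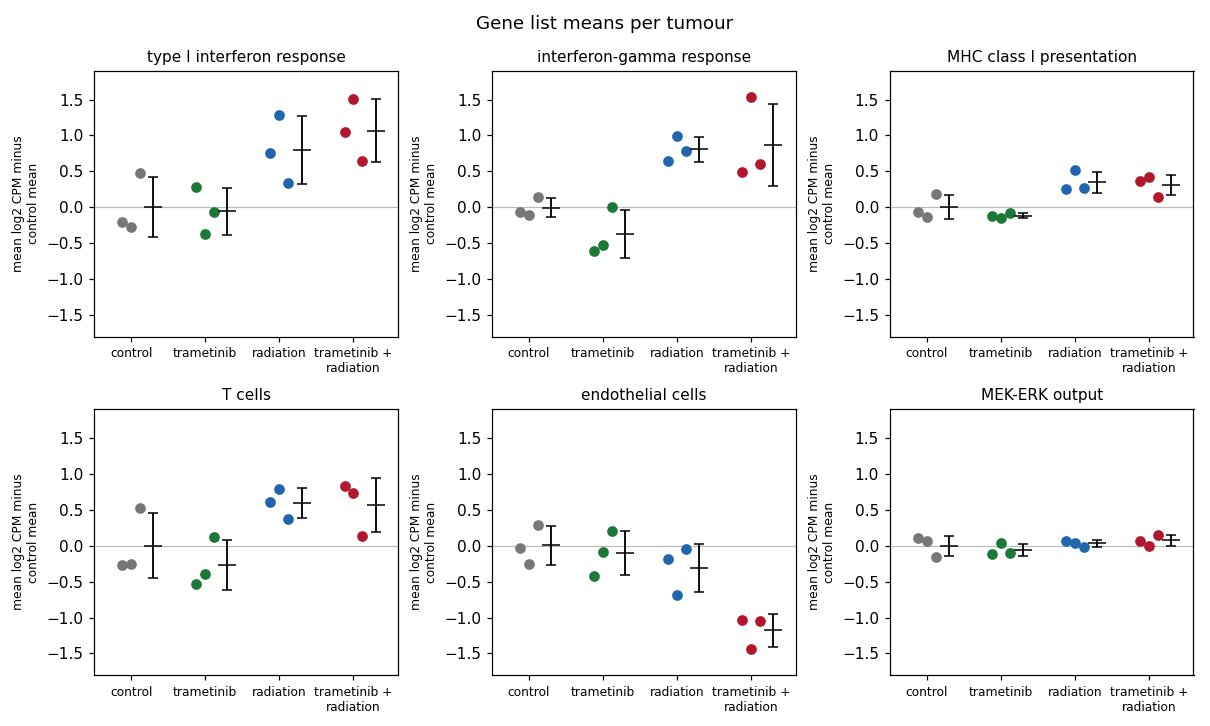
Mean log2 CPM of 6 gene lists in each of 12 tumours, minus the control mean, by treatment group, with 1 point per tumour and the bar and whiskers for the mean and SD of 3 tumours. Combination tumours lay between 0.64 and 1.51 for the type I interferon list and between -1.44 and -1.04 for the endothelial list, where controls lay between -0.27 and 0.48 and between -0.25 and 0.29.

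The combination was compared with trametinib alone to give the effect of radiation in drug-treated tumours. Cd274 rose from 19.4 ± 1.71 to 59.7 ± 17.3 CPM (SD, n = 3), a log2 fold change of 1.62 (SE 0.22, adjusted p = 0.0119 by edgeR). In the interferon-gamma list 7 of 20 genes rose, 19 adjusted over the list alone, with a median of 1.34, including Gbp3 (1.49, SE 0.22), Gbp7 (1.33, SE 0.21) and Cxcl10 (2.14, SE 0.45, adjusted p = 0.0498), while Cxcl9 gave 0.89 (SE 0.24, adjusted p = 0.0974). Without combination 2 Cxcl10 gave 1.14 and the list median was 0.83, and Cxcl10 kept its call in 3 of 12 fits without a library. In the type I interferon list 4 of 25 rose, 24 adjusted over the list alone, with a median of 1.18, including Stat2 (1.24, SE 0.23) and Cmpk2 (1.54, SE 0.31). In the MHC class I list 3 of 23 rose, 11 adjusted over the list alone, with a median of 0.40. They were Nlrc5 (0.86, SE 0.14), Tapbpl (0.75, SE 0.13) and Tapbp (0.92, SE 0.17), and H2-K1, H2-D1 and B2m gave 0.33 (SE 0.14), 0.27 (SE 0.13) and 0.39 (SE 0.16) without passing. In the endothelial list 7 of 15 fell, 12 adjusted over the list alone, with a median of -1.14, including Egfl7 (-1.21, SE 0.19), Cldn5 (-2.07, SE 0.35) and the receptor kinase gene Tie1 (-1.57, SE 0.28). The 4 lists passed by camera at the preset correlation and by fry (adjusted p = 0.018, 0.0398, 0.018 and 0.018), with adjusted p = 0.21, 0.256, 0.21 and 0.21 with an estimated correlation. Without combination 2 or trametinib 2 the 4 lists held 0 calls, and without trametinib 3 they held 3, 0, 0 and 0. Leaving out trametinib 1, combination 1 and combination 3 left 1, 6 and 4 calls in the interferon-gamma list, 1, 0 and 1 in the type I list, 2, 2 and 2 in the MHC class I list and 6, 1 and 0 in the endothelial list. Leaving out control 1, control 2, control 3 and radiation 1 gave 4, 5, 11 and 6, then 0, 1, 7 and 1, then 3, 4, 6 and 3, and 5, 6, 9 and 7 in the same order of lists. Without radiation 2 the MHC class I list held 5, and with the replicate block the type I list held 0. In the same order DESeq2 called 14, 17, 8 and 10, voom 11, 19, 6 and 9 and limma-trend on TPM 11, 16, 9 and 3. The type I list held 7 without the filter and 8 with these groups alone, and the MHC class I list held 5 without the filter and 6 with the offsets.

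Single genes outside these lists also differed between the combination and trametinib alone. Lymphocyte genes that rose were the costimulatory receptor gene Cd28 (1.74, SE 0.35) and Klrk1 (1.11, SE 0.20), which encodes the receptor NKG2D, and Cd8a, Cd3e, Gzmb and Ifng gave 1.31 (SE 0.34), 1.31 (SE 0.35), 0.70 (SE 0.34) and 1.67 (SE 0.54) without passing. Cd28 kept its call in 3 and Klrk1 in 7 of 12 fits without a library. Cd28 was the single call among 20 T cell genes, where 9 of these fits and the replicate block gave 0, leaving out control 3 gave 3, DESeq2 7, voom 5, limma-trend on TPM 5 and these groups alone 2. Klrk1 was the single call among 19 cytotoxic and NK cell genes, with 2 without control 3, 4 by DESeq2, 3 by voom, 2 by limma-trend on TPM and 0 with these groups alone. Mdm2 rose by 0.74 (SE 0.13), while Cdkn1a and Ccng1 both gave 0.07 (SE 0.10 and 0.12). Besides Cxcl10, the largest rises under the naming rule, with its limits on CPM and overlap, were in the amino acid transporter gene Slc7a2 (1.91, SE 0.39), Dynap (1.75, SE 0.35), Apol6 (1.70, SE 0.35) and Mfap3l (1.69, SE 0.28). The largest falls under that rule were in Fcrls (-4.00, SE 0.84), Car6 (-2.30, SE 0.29), Depp1 (-1.95, SE 0.24), Gpihbp1 (-1.85, SE 0.28), which anchors lipoprotein lipase on capillary endothelium, and Vash1 (-1.79, SE 0.32), an endothelial regulator of vessel growth. In the MEK-ERK output list the phosphatase gene Dusp4 rose (0.83, SE 0.17), while Dusp6, Etv4 and Spry4 gave -0.15 (SE 0.19), 0.28 (SE 0.10) and 0.09 (SE 0.22). For each called gene all 3 combination tumours lay on one side of the 3 trametinib tumours, at adjusted p of 0.0119 to 0.0498 by edgeR. The naming rule required this separation of the largest rises and falls. Among 13567 genes 122 were called, 70 up and 52 down, against 477 by DESeq2, 324 by voom and 200 by limma-trend on TPM. The count was 0 without combination 2, 1 without trametinib 2, 24 without trametinib 3, 37 without combination 3, 39 without combination 1, 61 without control 1, 67 without trametinib 1, 74 without radiation 1, 79 without control 2 and 201 without control 3. In that order 0, 1, 7, 11, 10, 16, 12, 17, 19 and 25 of the 25 called genes named for this comparison kept their call, as did 24 without radiation 2 and 23 without radiation 3.

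The combination was compared with radiation alone to give the effect of trametinib in irradiated tumours. Endothelial genes were lower in all 3 combination tumours than in all 3 irradiated ones, without passing edgeR's test over all genes, with values of -1.71 (SE 0.35) for Cldn5, -1.24 (SE 0.24) for Emcn, -1.22 (SE 0.25) for Esam and -0.93 (SE 0.19) for Egfl7, each at adjusted p = 0.314 by edgeR. By DESeq2 6 of 15 endothelial genes were called down over all genes, by edgeR and voom 0. When adjusted over the list alone 12 of 15 were lower by edgeR, and the list median was -0.93 (camera's adjusted p = 5.66e-17, adjusted p = 0.414 with an estimated correlation). Cd274 gave 0.26 (SE 0.21) and Mdm2 0.40 (SE 0.13). The MHC class I, interferon-gamma and T cell lists had medians of -0.06, 0.17 and 0.01 with camera's adjusted p of 0.566, 0.641 and 0.988, and the type I interferon list had 0.24 (camera's adjusted p = 0.00298, adjusted p = 0.807 with an estimated correlation). These medians were not stable in fits without 1 library. The interferon-gamma median ranged from -0.30 (without combination 2) to 0.38 (without combination 1) and the type I median from 0.00 (without combination 2) to 0.49 (without radiation 2). The MHC class I median ranged from -0.11 (without combination 1) to 0.05 (without combination 3) and the T cell median from -0.14 (without combination 2) to 0.17 (without combination 3). By edgeR 0 of 13567 genes passed, with 828 at an unadjusted p below 0.05, 27 calls by DESeq2, 0 by voom and by limma-trend on TPM, and 1 with these groups fitted alone.

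Radiation averaged over both drug states set 6 irradiated tumours against 6 others. Cd274 rose by 1.35 on the log2 scale (SE 0.15, adjusted p = 0.00353 by edgeR), from 23.6 ± 4.67 and 19.4 ± 1.71 CPM in control and trametinib tumours to 50.0 ± 11.7 and 59.7 ± 17.3 with radiation (SD, n = 3). In the type I interferon list 22 of 25 genes rose, 24 adjusted over the list alone, with a median of 1.07, including Stat2 (1.18, SE 0.17) and Oasl2 (1.23, SE 0.21). In the interferon-gamma list 18 of 20 rose, 20 adjusted over the list alone, with a median of 1.06, including Gbp3 (1.15, SE 0.15), Gbp6 (1.24, SE 0.18), Tgtp1 (1.43, SE 0.27) and Cxcl10 (1.42, SE 0.32, and 0.92 without combination 2), while Cxcl9 gave 0.45 (SE 0.17, adjusted p = 0.11). In the MHC class I list 10 of 23 rose, 17 adjusted over the list alone, with a median of 0.36. They included Nlrc5 (0.77, SE 0.10), Tap2 (0.69, SE 0.11), the peptide-trimming enzyme gene Erap1 (0.47, SE 0.07), H2-K1 (0.39, SE 0.10) and B2m (0.47, SE 0.11), and H2-D1 gave 0.30 (SE 0.09, adjusted p = 0.0603). Endothelial genes fell in 8 of 15 cases, 11 adjusted over the list alone, with a median of -0.68, including Cldn5 (-1.53, SE 0.24) and Egfl7 (-0.91, SE 0.14). That average joins an endothelial median of -0.23 with 0 calls for radiation against control (from -0.42 without control 2 to -0.02 without radiation 2) and of -1.14 with 7 calls for the combination against trametinib. By camera at the preset correlation these 4 lists passed, with adjusted p = 0.321, 0.257, 0.257 and 0.321 with an estimated correlation, and by fry with adjusted p = 0.0139, 0.00558, 0.00558 and 0.0139. Over the 12 fits without a library the calls ranged from 11 (without control 2) to 23 (without control 3), from 12 (without control 2) to 18, from 8 to 15 (without control 3) and from 5 (without trametinib 2 or 3) to 8 in these lists. The type I list also held 14 calls without trametinib 2 or radiation 2, the MHC class I list 16 by voom and 20 by limma-trend on TPM, and the endothelial list 5 by limma-trend on TPM. For the called genes named here, except Cldn5 and B2m, all 6 irradiated tumours lay on one side of the 6 others, which the naming rule required of Tgtp1. By list means, the type I, MHC class I and endothelial lists overlapped between irradiated and other tumours, and the interferon-gamma list did not. Control 3 lay at 0.48 and 0.19 in the type I and MHC class I lists, above radiation 3 at 0.34 and combination 3 at 0.15.

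Part of the lymphocyte genes rose with radiation averaged over both drug states. In the T cell list 8 of 20 rose, 11 adjusted over the list alone, with a median of 0.76, including Cd8a (1.22, SE 0.24), Cd3e (1.09, SE 0.24) and Themis (1.11, SE 0.21). In the cytotoxic and NK cell list 6 of 19 rose, with 9 up and 1 down adjusted over the list alone, including Gzmb (0.91, SE 0.24), Ifng (1.52, SE 0.37) and Klrk1 (0.80, SE 0.14). In the checkpoint list 7 of 18 rose, 14 adjusted over the list alone, including Cd274 and Lag3 (1.14, SE 0.22). Both lymphocyte lists gave adjusted p = 0.328 with an estimated correlation and 0.025 by fry, and the checkpoint list gave 0.257 and 0.00558. The chemokine receptor gene Cxcr6, expressed by activated T cells, rose by 1.51 (SE 0.24). With it Slfn4 (1.76, SE 0.31), Apol6 (1.63, SE 0.24), Pthlh (1.58, SE 0.28) and Tgtp1 were the 5 largest rises under the naming rule, with its limits on CPM and overlap. The largest falls under that rule were in Car6 (-2.11, SE 0.21), the sulfotransferase gene Sult1a1 (-1.76, SE 0.24), the carbonyl reductase gene Cbr2 (-1.58, SE 0.32), the casein gene Csn3 (-1.44, SE 0.20) and Avil (-1.29, SE 0.20). Of 20 p53 targets 2 rose and 1 fell, with Mdm2 at 0.58 (SE 0.09) and Sesn1 at -0.41 (SE 0.11), while Cdkn1a and Ccng1 gave 0.09 (SE 0.07) and 0.07 (SE 0.08). In the hypoxia and glycolysis list 2 of 22 rose, the hexokinase gene Hk2 (0.85, SE 0.16) and the histone demethylase gene Kdm3a (0.39, SE 0.09), with a list median of 0.52 (camera's adjusted p = 5.55e-05, adjusted p = 0.539 with an estimated correlation). By edgeR 1049 genes were called, 542 up and 507 down, at adjusted p of 0.00162 to 0.0465 for the named ones, against 1793 by DESeq2 and 2418 by voom. The T cell list held 4 calls without control 2 or trametinib 2 and 5 without control 1, radiation 1, radiation 2 or combination 1. The cytotoxic list held 2 without trametinib 2, 3 without control 2 or radiation 2 and 10 without control 3. By limma-trend on TPM the T cell list held 13, and by voom the cytotoxic list held 11 up and 1 down. For Cd8a, Cd3e, Gzmb, Hk2 and Sesn1 the irradiated and other tumours overlapped. Leaving out control 2 left 348, trametinib 2 436, combination 3 545, trametinib 3 553, radiation 1 640 and radiation 2 645, and control 3 gave 1651. Of 34 called genes named for this contrast 27 kept their call in each of 12 such fits, and H2-K1, B2m, Cd3e, Ifng, Gzmb, Cxcl10 and Sesn1 did so in 4, 6, 10, 5, 3, 10 and 1 of them.

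**Figure D2:**
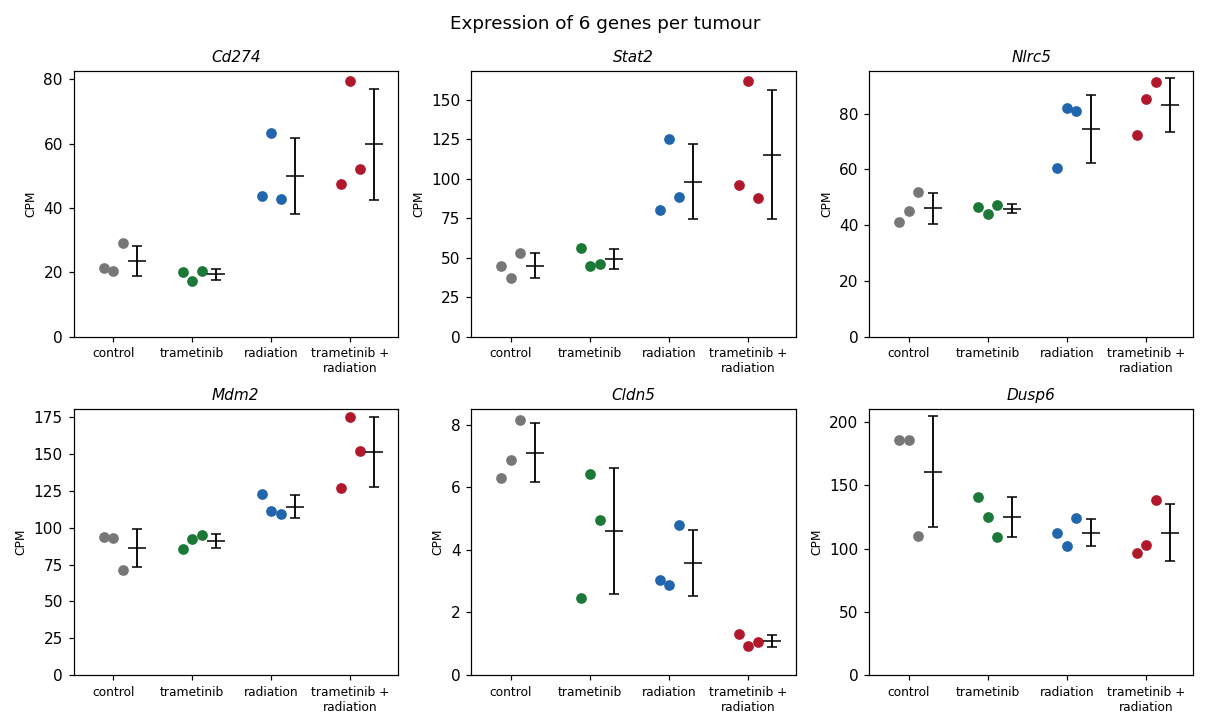
Expression in CPM of Cd274, Stat2, Nlrc5, Mdm2, Cldn5 and Dusp6 in each of 12 tumours by treatment group, with 1 point per tumour and the bar and whiskers for the mean and SD of 3 tumours. Mean Cd274 was 23.6 CPM in controls and 59.7 CPM in the combination, and mean Cldn5 was 7.11 and 1.10 CPM.

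By edgeR, trametinib averaged over both radiation states gave no calls, and neither did the interaction, which tests whether the effect of radiation differed between drug states. Averaged over radiation, Cd74 gave -0.70 (SE 0.14), H2-Eb1 -0.78 (SE 0.17), H2-Aa -0.69 (SE 0.15), Cldn5 -1.16 (SE 0.24) and Dusp6 -0.18 (SE 0.14), at adjusted p of 0.233 to 0.626 by edgeR. When adjusted over the list alone 9 of 10 MHC class II genes and 8 of 15 endothelial genes were lower, and each list had adjusted p = 0.501 with an estimated correlation. Over all genes DESeq2 called 5 of the former and 4 of the latter down, and edgeR called 0. The interaction was -1.26 (SE 0.38) for Tie1 and -0.85 (SE 0.27) for Pecam1, both endothelial genes, and 1.43 (SE 0.62) for Cxcl10 and 0.54 (SE 0.30) for Cd274, each at adjusted p = 0.998. In the endothelial list 6 of 15 genes had a negative interaction when adjusted over the list alone, with a median of -0.91 (camera's adjusted p = 1.55e-10, adjusted p = 0.605 with an estimated correlation, 0.573 by fry). By edgeR 0 genes passed for the averaged trametinib effect, with 1504 at an unadjusted p below 0.05, and 0 for the interaction, with 547. DESeq2 called 66 and 2, and voom and limma-trend on TPM called 0 for both.

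The effects of radiation without and with the drug share no library, and across 13567 genes, which are not independent replicates, their log2 fold changes correlated with Pearson's r of 0.47 and Spearman's rho of 0.52. Of the 122 genes called in the combination against trametinib 121 had the same sign in radiation against control, 78 of them at an unadjusted p below 0.05. Comparisons against the same 3 controls are correlated by those controls. The correlation was 0.742 between radiation and the combination (0.51, SD 0.021, in 20 simulated draws of unchanged groups), 0.59 between trametinib and the combination (0.501, SD 0.023) and 0.53 between trametinib and radiation (0.506, SD 0.026), the last within 1 SD of the simulated value. The covariances were 0.197, 0.114 and 0.0964 against simulated values of 0.0564 (SD 0.00324), 0.0551 (SD 0.00353) and 0.056 (SD 0.00407). The differences of 0.14, 0.0585 and 0.0404 were each beyond the simulated spread, so for trametinib and radiation the covariance exceeded the simulated one while the correlation did not. Genes were drawn independently in these simulations, so the spread for genes that move together can be wider, and no shared treatment effect follows. The controls are too few to be split, so part of each excess can come from them. Tnc was the 1 gene called both in radiation and in the combination against control, and 740 of the 1049 genes called for averaged radiation were also called in the combination against control, comparisons that share libraries.

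Among the authors' deposited q-values, 37 genes had q below 0.05 for trametinib against control, 266 for radiation, 1348 for the combination, 27 for the combination against radiation and 432 for the combination against trametinib. Of these, 0, 1, 1040, 0 and 118 were called here too, with the same sign in each case, so the equal totals of 1348 for the combination against control count different sets. On the TPM scale the median of all genes shifted by 0.23 on the log2 scale in the combination against control, 0.16 in radiation against control, 0.12 in the combination against trametinib and 0.14 for averaged radiation. With that shift, 91.3% of calls in the combination against control were rises by limma-trend on TPM, against 48.4% by edgeR on counts. For the combination against trametinib the shares were 87.5% and 57.4%, and for averaged radiation 89.2% and 51.7%. The shift also enters the list medians and list calls on TPM given above.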

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

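Tests of muscle tissue in control 3 and of T cell RNA against the interferon genes, of stroma share against the endothelial genes, and of GC content and of library length trends were chosen after the results were seen, as were the offsets for length and GC content. The tests on other splits of the samples were planned.

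In 8 gene lists the interaction of radiation and trametinib passed by camera at the preset correlation, but none of the 8 passed with an estimated correlation (adjusted p of 0.605 to 0.916) or by fry, and edgeR called 0 genes for it. The median interaction on the log2 scale was 0.48 for MHC class II, 0.39 for type I interferon, 0.49 for interferon-gamma, -0.26 for fibroblasts and matrix, -0.91 for endothelial cells, 3.33 for adipocytes, -2.43 for red blood cells and -0.41 for hypoxia and glycolysis. The red blood cell list stood out for a second reason, since the 3 irradiated tumours lay above the control mean, by 1.53 to 1.89, while the 3 combination tumours, at -0.95 to 1.26, lay below the trametinib mean of 2.06. The difference of -3.94 between the radiation effects with and without the drug is the interaction of that list mean, and the list's interaction did not pass with an estimated correlation (adjusted p = 0.605) or by fry (0.573). Controls alone spread from -2.13 to 2.95 in that list.

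Interferon and MHC class I genes were higher with radiation averaged over trametinib, with a median log2 fold change of 0.87 over 68 genes, 50 of them called. Control 3 lay highest of the controls in the type I interferon, interferon-gamma and MHC class I list means (0.48, 0.15 and 0.19). Leaving it out could thus only raise the difference of list means, and the median was 0.94 with 49 of the 50 genes still called. That fit is therefore no test of muscle tissue in control 3. It shows only that low values in this library did not produce the rise. Length and GC bias as the whole cause is argued against by the fit with offsets, where the median was 0.91 and 46 kept their call. More T cell RNA cannot be told apart from a response in other cells, because the mean of the interferon lists rose by 0.99 (SE 0.20) and that of the T cell list by 0.71 (SE 0.21), a difference of 0.27 (SE 0.16). An effect of radiation on interferon genes in tumour or stromal cells was not tested apart from T cell content, which expression in sorted cells would decide.

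Endothelial genes were lower in the combination than in control, with a median log2 fold change of -1.26 over 15 genes and 9 called. With length and GC offsets the median was -1.35, without control 3 it was -1.10, and all 9 called genes kept their call in both fits, which argues against length bias and against vessels of muscle tissue in that control as the whole cause. A lower share of stroma as a whole would lower fibroblast genes alike, but the endothelial list mean fell by 1.49 (SE 0.30) against the fibroblast list mean, an estimate of -1.49. The tested technical explanations are thus argued against, and whether fewer endothelial cells or lower expression in them under both treatments lies behind the pattern was not tested, which vessel counts in stained sections would decide. Without control 2 the fit called 2 of the 15 genes and without combination 3 it called 5, while the medians were -1.41 and -1.32.

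Longer transcripts were higher and shorter ones lower in the combination than in control (rho of 0.39 across genes). The median length was 5000.5 bases for rises and 1829 for falls against 3383 for tested genes. The rho was 0.31 for trametinib and 0.30 for radiation against control, and 0.32 for averaged radiation, with 4215 and 1938 bases. These contrasts share the control libraries, whose own length trends were the lowest, so they do not show a trend of each treatment. In contrasts without controls the rho was 0.25 for the combination against radiation and 0.28 against trametinib. The length trends of the irradiated tumours without drug (-0.12 to 0.27) overlapped those of the combination (0.11 to 0.43), and those of trametinib alone (-0.11 to 0.05) did not. GC content as the driver is argued against by a partial Spearman correlation across genes of 0.12 with GC content given length, against 0.40 with length given GC content. Ribosomal protein genes had a median log2 fold change of -0.53 over 82 genes, -0.27 from that of genes matched on length (-0.26, with 95% of 1000 draws between -0.35 and -0.17). Of all 83 ribosomal protein genes 44 were called down, and 11 were with the offsets, where their median was -0.28. Lengths were those of the longest annotated transcript, which need not be the expressed one, and expression level was not matched. Whether a length trend alone moved ribosomal protein genes therefore cannot be decided. RNA recovery that differs by library cannot be told apart from the treatment, since the length trends of the 3 controls (-0.30 to -0.19) and the 3 combination tumours (0.11 to 0.43) did not overlap but the exact permutation test, two-sided, gave p = 0.1, the smallest that 3 against 3 allows.

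Counts of called genes were set against other splits of the same libraries. With 3 against 3 libraries there are 10 splits, too few for a share below 0.05. The real split gave 0 calls for trametinib against control (10 of 10 splits as many, highest other 0), 1 for radiation against control (1 of 10, highest other 0), 1348 for the combination against control (1 of 10, highest other 1), 0 for the combination against radiation (10 of 10, highest other 0) and 122 for the combination against trametinib (1 of 10, highest other 2). For radiation averaged over trametinib, only the real split, 1 of 100, gave as many as 1049, with 190 as the highest other. At this number of splits that argues against a random division of the libraries as the source of that count, without excluding it. For averaged trametinib and the interaction the real count was 0, which each of 100 splits reaches by construction (100 of 100, highest other 184 and 902), so the splits decide nothing there. Counts so far above the real ones point to a structure of the samples. In the split with 902 calls all 6 irradiated libraries stood on one side of the contrast, so it counted the averaged radiation effect, while the split with 184 calls did not follow the treatments and its source was not tested.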

How the results depend on the processing

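All alternatives but the length and GC offsets were planned, and those offsets were chosen after the data were examined. For the 168 pairs of a gene and a contrast named here, fits without 1 library gave the same direction and side of the threshold in 1702 of 2016 cases, were no longer past it in 285, newly past it in 12 and of opposite sign in 17. The other alternatives gave 1170, 55, 64 and 4 of 1293. Opposite signs were confined to values near 0 that did not pass. Cxcl9 in the combination against control gave 0.08 on TPM, Etv4 there -0.02 by voom, Cxcl9 in radiation against control 0.00 by DESeq2 and B2m in trametinib against control 0.13 with the offsets. Without 1 library, Etv4 in the combination against control ranged from -0.05 to 0.10, Spry4 there from -0.09 to 0.36, Spry4 in the combination against trametinib from -0.16 to 0.29, Cxcl9 in radiation against control from -0.16 to 0.23, Ccng1 there from -0.05 to 0.15, Spry4, H2-K1 and H2-D1 in trametinib against control from -0.01 to 0.22, -0.03 to 0.12 and -0.05 to 0.11, and Cd274 in the combination against radiation from 0.00 to 0.47. Counts of called genes in the order trametinib, radiation and combination against control, combination against radiation and against trametinib, averaged trametinib, averaged radiation and interaction were 31, 510, 2051, 27, 477, 66, 1793 and 2 by DESeq2. Counts that moved by over 1.5 times were, by voom, 1 for trametinib, 1123 for radiation, 2350 for the combination, 324 for the combination against trametinib and 2418 for averaged radiation, on TPM 44, 2120 and 200 for radiation, combination and combination against trametinib, with these groups alone 2, 281 and 1 for radiation, combination and combination against radiation, 5 for radiation without the filter, and 453 for the combination with the offsets. Without 1 library they ranged from 0 (without control 1 or radiation 1) to 425 (without control 3) for radiation, from 16 (without control 2) to 1502 (without control 3) for the combination, from 0 (without combination 2) to 201 (without control 3) for the combination against trametinib and from 348 (without control 2) to 1651 (without control 3) for averaged radiation, and stayed at 0 for the other 4. Fits without a library have fewer samples, and the cause of the other differences was not tested. Lists past the threshold by camera numbered 9, 13, 12, 11, 12, 9, 12 and 8 in that order, 0 with an estimated correlation in each contrast, and 0, 0, 1, 0, 6, 0, 8 and 0 by fry. With the replicate block the gene counts were 0, 3, 1069, 0, 89, 0, 896 and 0. Deviations of libraries with the same number correlated at -0.18 to 0.31 (median 0.06, 7 of 18 pairs over 0.1). Those of libraries with different numbers correlated at -0.29 to 0.26 (median -0.02). The difference was not tested, so some sharing by number cannot be excluded, and the main fit treated the numbers as not pairing the tumours. Small changes can be missed with 3 tumours per group. In simulated data with 200 genes changed, for genes with a mean log2 CPM above 2, the test recovered 35.8% of 1.5-fold changes for trametinib against control and 3% for the interaction. Recovery can be lower in the real contrasts with 0 calls, where the adjusted threshold is stricter.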

Other observations

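Lists for muscle and fat tissue differed widely between libraries of the same group. Relative to the control mean, the skeletal muscle list lay at -2.67, -1.08 and 3.75 in the 3 controls and between -3.05 and 0.63 in the other 9 tumours, and 0 of 18 genes rose or fell with radiation averaged over trametinib. The adipocyte list lay at -2.80 ± 0.77 (SD, n = 3) with radiation and -1.45 ± 1.52 with the combination, where controls spread from -1.95 to 1.63. With radiation averaged over trametinib 2 of 10 adipocyte genes fell, 7 adjusted over the list alone, with a median of -2.44 (adjusted p = 0.459 with an estimated correlation).

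Myeloid lists and proliferation gave smaller values. The neutrophil list lay at 0.70 ± 0.80 with radiation, -0.64 ± 0.63 with trametinib and -0.15 ± 0.31 with the combination relative to controls (SD, n = 3), and 2 of 18 genes rose with averaged radiation (list median 0.42, adjusted p = 0.517 with an estimated correlation). The dendritic cell list lay at -0.59 ± 0.22 in the combination, where 0 of 14 genes were called by edgeR over all genes or adjusted over the list alone, with adjusted p = 0.578 with an estimated correlation. With averaged radiation 0 of 28 DNA repair genes and 0 of 36 cell cycle genes were called, with medians of 0.02 and -0.02 and camera's adjusted p of 0.986 and 0.897. The list of immediate early and heat shock genes, which respond to tissue handling, had a median of 0.16 with averaged radiation, 0 of 15 genes called and camera's adjusted p = 0.258.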
